A study of Drosophila melanogaster with 2 samples.

How the data were processed

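Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex, 0 to 16 hours old, per the labels. The flies came from a line labelled transgenic that expresses the transcription factor Gcm (glial cells missing) fused at its C-terminus to green fluorescent protein, and an antibody against that protein was used for the precipitation. Chromatin was sheared by sonication, with a labelled size range of 200 to 800. The labels name 2 biological replicates, numbered 1 and 3, which form 1 group, so the design holds no comparison between groups. Both carry the same donor label, and p-values over peaks or genes say nothing about the spread between flies.

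The authors deposited 4 peak lists on the genome build dm6. Each replicate has a list called on that replicate alone, the pooled list was called on the alignments of both, and the IDR-thresholded list was derived from the other 3, per the file descriptions deposited with them. IDR, the irreproducible discovery rate, measures how repeatable the ranks of peaks are between replicates. All lists used the same control file, which was not analysed here. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The peak height is a signal value that the authors' caller gave to each peak, never negative, on a scale that differs between lists. The deposited −log10 q-value of each peak has a ceiling (4.28 in the pooled list), and every peak of the IDR-thresholded list sits at it, so it was not used for ranking. The p-value column holds the placeholder -1 in every row of the deposited lists and was not used. These scores are the authors' own and served only to describe and rank peaks within a list. Read depth is unknown here, since a peak list holds no library totals.

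The replicate lists and the pooled list held 30000 peaks each and the IDR-thresholded list 5707. Every IDR-thresholded peak was found unchanged in the pooled list, where these were the 5707 peaks of highest signal. Replicates were therefore compared through their own 5707 strongest peaks. Peaks are not replicates, and each 95% interval given covers counting error only. Intervals of a share are exact Clopper-Pearson intervals. Those of a difference between shares use the normal approximation, and those of an odds ratio are conditional exact intervals. A value given as mean ± SD is over the 2 replicates' own lists. Of the IDR-thresholded peaks, 77 shared their interval with another peak and differed in the summit, and these were kept.

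Positions are 1-based on dm6. Genes, exons and transcription start sites (TSS) came from Ensembl release 115 (BDGP 6.54) and sequence from the Release 6 assembly, which has the same coordinates, and 0 peaks lay past the end of an arm. The arms 2L, 2R, 3L, 3R, 4 and X were used, with 13945 protein-coding genes. A summit within 500 bp of a protein-coding TSS was called promoter, and other summits were called 5' UTR, coding exon, 3' UTR, intron or intergenic. A gene was called bound when a summit lay in its body or up to 2000 bp upstream. Symbols Dl and h were matched by gene identifier to the annotation's Delta and hry.

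Overlap of the replicates' top peaks (at least 1 bp) was set against 100 random placements on the same arm. Height was compared by Spearman's rho across peaks. Annotation shares were set against 20 random positions per peak by Fisher's exact test, and arm shares against arm length by an exact binomial test. Motifs were sought on both strands within 100 bp of the summit and in an equal window 1000 bp to the left, and compared by the exact McNemar test. Peak heights with and without the Gcm motif were compared by a permutation test with 100000 resamples. Bound genes per list were tested by permutation, against 10000 random lists drawn with list membership permuted within 20 bins of territory length. This treats genes as independent, though some members of a list are neighbours, such as E(spl) genes on arm 3R. The p-values of such lists may be too small. All tests were two-sided, the threshold was 0.05, and Benjamini-Hochberg adjustment was applied within each family (13 lists, 12 motifs, 6 arms, 6 annotation classes).

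The design, the tests, the other settings tried, the named-gene rule, 13 gene lists and 12 motifs were chosen before the data were examined. The rule named gcm, gcm2, repo, pnt, loco and ttk whatever their values, the nearest TSS of the 10 highest peaks, up to 4 members per list with the highest peak, and the 5 genes with most summits. Of the genes it named, 1 is not reported here. The glial list held gcm, gcm2, repo, pnt, loco, ttk, moody, Gli, nrv2, wrapper, htl, Eaat1, Gs2, alrm, Nrx-IV, Cont, Mdr65, bnb, Nrg, drpr, kune, sinu and Lac. The plasmatocyte list held srp, ush, Pxn, crq, NimC1, NimC4, Hml, eater, Sr-CI, Pvr, vkg, Col4a1, Ppn, SPARC, glec, He, ItgaPS4, Nplp2, Tig, Glt and LanB1, and the crystal cell list lz, PPO1, PPO2, PPO3, peb and klu. The neuron list held elav, nSyb, Syt1, brp, fne, para, cac, ChAT, VGlut, Gad1, futsch, Rbp9, Syx1A, Snap25, cpx, VAChT, Vmat, Rdl, ple and Ddc. Neural precursor genes were dpn, ase, wor, pros, scrt, sna, esg, insc, mira, brat, numb, ac, sc, l(1)sc, SoxN, D, nerfin-1, grh, cas, hb, Kr, nub, pdm2 and svp. Notch pathway genes were N, Delta, Ser, Su(H), H, the E(spl) genes m3, m5, m7, m8, mbeta, mgamma and mdelta, neur, mam, kuz, fng, Brd and Tom. Hedgehog pathway genes were hh, ptc, smo, ci, cos, fu, Su(fu), disp, ihog, boi and rasp, and JAK/STAT pathway genes dome, hop, Stat92E, upd1, upd2, upd3, Socs36E, Socs44A, Ptp61F, et, Su(var)2-10 and ken. The muscle list held Mhc, Mef2, tin, bap, twi, nau, sls, Act57B, Act87E, up, wupA, Tm1, Tm2, Mlc1, Mlc2, how, if, bt, Mp20, kirre, rst, sns, blow and lmd. The trachea and epidermis list held trh, btl, vvl, salm, rho, pnr, shg, crb, bnl and sim, and the early patterning list eve, ftz, hry, odd, prd, slp1, run, opa, en, wg, dpp, gt, kni, tll, hkb, bcd and cad. The last lists were all symbols of cytoplasmic ribosomal proteins (RpL and RpS) and of odorant and gustatory receptors (Or and Gr). A further 8 lists, for Hox genes, the Wnt and EGF receptor pathways, nuclear receptors, the respiratory chain, cuticle proteins, trypsin-like proteases and septate junctions, were written after the peak files had been opened and before any list was tested.

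The motifs were Gcm ATRCGGGY, GAGA factor GAGAGAG, Zelda CAGGTAG, GATA factor WGATAR, Runt TGTGGTY, ETS CCGGAAGT, Stat92E TTCNNNGAA, Su(H) YGTGRGAA, DRE TATCGATA, E-box CAGCTG, M1BP GGTCACACT and homeodomain TAATTA.

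Alternatives covered the strongest 2853 peaks, each replicate alone, other overlap rules, other promoter widths (250 and 1000 bp), gene numbers in place of arm length, other motif windows (50 and 250 bp each side), the right flank, random windows matched on GC content within 2 percentage points, a stricter Gcm word, other gene territories and Fisher's exact test without length matching. Splitting peaks by the Gcm motif or by promoter, gene numbers for arms other than X, and the motif count with 250 bp each side were added after the results had been seen.

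The steps were tested on simulated data. With the Gcm word planted in 9.37% of windows, 9.46 percentage points were recovered over the flank, and 0 of 12 motifs had an unadjusted p under 0.05 with nothing planted. These windows lay at random positions, so the check does not cover differences in composition between real summits and their flanks. With 59.5% of top peaks made shared, 61.6% were found overlapping. In the list test, 3.5% of random lists of 20 genes had an unadjusted p under 0.05, as did 78.5% of lists whose bound genes were drawn at 4 times the weight. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.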

Results

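Binding of Gcm, the zinc-dependent transcription factor that directs glial fate in the fly nervous system and acts in embryonic blood cells, was mapped in whole embryos aged 0 to 16 hours. The group held 2 biological replicates, numbered 1 and 3, of a line expressing Gcm fused to green fluorescent protein. Each replicate's list held 30000 peaks, and the IDR-thresholded list made from both held 5707. Median signal was 50.9 in replicate 1, 42.6 in replicate 3 and 299 in the IDR-thresholded list, where it ran from 190 to 5118.

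The first question was whether the replicates placed the protein at the same sites. The highest peak of both lay 128 bp from the TSS of Fkbp14, a prolyl isomerase gene, with signal 2864 in replicate 1 and 2232 in replicate 3. The next highest, at px, ranked 2 in each. Of the 5707 strongest peaks of replicate 1, 80.1% overlapped one of replicate 3, and 81.1% did so in the other direction. These are both directions of a single comparison and give no spread between replicates. Random placement gave 2.66% on average and at most 3.31% (permutation p = 0.0099, the smallest that 100 placements can give). Placement was uniform along each arm, so any shared preference for regions such as promoters would also exceed it. The test cannot tell such a preference from binding of the protein at the same sites. Heights of the 5649 IDR-thresholded peaks found in both lists had a Spearman's rho of 0.763 across peaks, which are not independent replicates, and the median ratio of replicate 1 to replicate 3 was 1.27. The IDR-thresholded peaks were the 5707 of highest signal in the pooled list, which was called on both replicates. This rho therefore describes a set cut by height and is no independent measure of how far the replicates match.

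**Figure D1:**
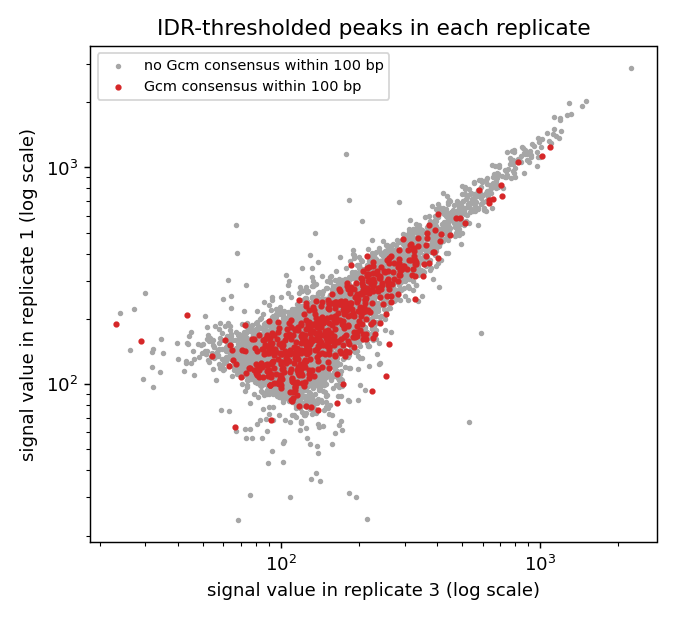
Signal value of each IDR-thresholded peak in replicate 3 (x axis, log scale) and replicate 1 (y axis, log scale). Each point is 1 peak, red where the Gcm consensus lies within 100 bp of the summit, and rho was 0.763 over 5649 peaks.

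Most of the 10 highest peaks lay at promoters. Fkbp14 (arm 2R, 21496891 to 21497855, intron of the gene) had a signal of 5118, which was 17.1 times the median. The peak at px, a wing vein gene (2R, 22514021 to 22514546), reached 3518. In the intron of CG11050 (2L, 6612385 to 6612946) it was 3369. The peak nearest the TSS of cbt, a zinc finger gene (2L, 480843 to 481438), lay in an intron of the neighbouring gene ush, 1383 bp away, at 3309. Promoter peaks of CG14100, CG18549, the sugar transporter gene Ugalt, the methyltransferase gene Art3 and CG11309 ranged from 2825 to 3082. The last, at 2684, was intergenic and 11917 bp from the nearest TSS, that of CG13323. None of these 10 had the Gcm consensus within 100 bp of its summit.

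Genes known in connection with gcm were bound at lower rank. Its paralogue gcm2 had 3 summits, the highest (2L, 9608004 to 9608681) 198 bp upstream of the TSS with signal 1341, rank 117 of 5707, and the Gcm consensus. The glial homeodomain gene repo had 2, the higher (3R, 18235837 to 18236315) 105 bp upstream at 787 and rank 427. The ETS factor gene pnt had 14, led by an intronic peak with the consensus (3R, 23309762 to 23310246) at 638 and rank 701. At gcm itself 1 summit (2L, 9581597 to 9581942) lay 58 bp upstream at 552 and rank 937, ranking 796 in replicate 1 and 1200 in replicate 3. The intronic peak of loco, which encodes a regulator of G protein signalling (3R, 22627972 to 22628466), had the consensus, a signal of 509 and rank 1132. The repressor gene ttk had 2 summits, the higher at 281 and rank 3155, in an intron 373 bp from an internal TSS.

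**Figure D2:**
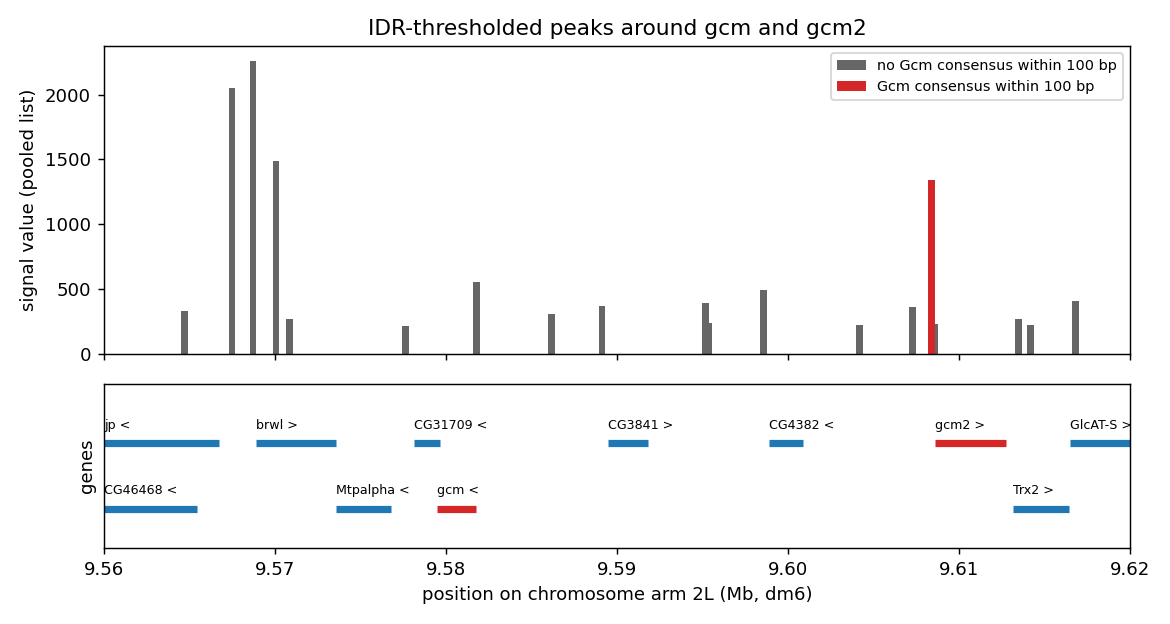
Signal value of the IDR-thresholded peaks (y axis, pooled list) by position on arm 2L (x axis, Mb, dm6), with genes drawn to scale below. The peak at gcm2, at 1341, is the one with the Gcm consensus, and the peak at brwl reaches 2263.

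Most summits lay at promoters and in introns. Promoters held 39.5% of summits (2253, interval 38.2 to 40.8) against 11.5% of random positions, a ratio of 3.43 (40.2% ± 0.508 over the replicates, n = 2). Introns held 38.4% against 39.4% (Fisher's exact adjusted p = 0.132). Coding exons held 1.21% against 14.1% (Fisher's exact adjusted p = 1.04e-261), 3' UTRs 1.07% against 4.37% (8.68e-46) and intergenic sequence 19.2% against 30.01% (3.57e-73), while 5' UTRs, at 0.666% against 0.590%, did not pass (0.479). The promoter p was too small for the software to represent. Summits lay a median of 1133 bp from a TSS, and random positions 4266 bp.

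**Figure D3:**
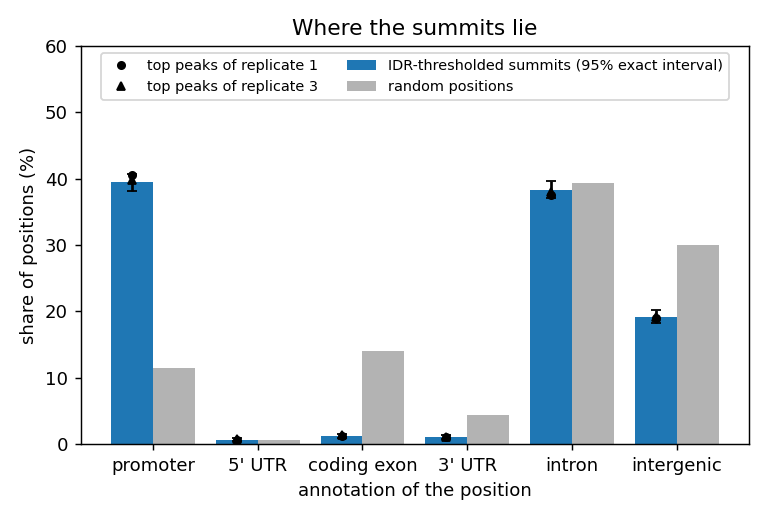
Share of positions in % (y axis) by annotation class (x axis) for IDR-thresholded summits (blue, exact 95% interval), random positions (grey) and each replicate's top peaks (points). Promoters stand at 39.5% against 11.5%.

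Chromosome 4, the small and largely heterochromatic arm, held 22 peaks, 0.385% of the total against 1.01% of the length (exact binomial adjusted p = 7.99e-07), and 0.447% ± 0.0124 of the replicates' top peaks (n = 2). Arm 2L held 19.0% of peaks against 17.6% of length (exact binomial adjusted p = 0.00966). The X chromosome held 15.8% (15.7% ± 0.0372, n = 2) against 17.6% of length (exact binomial adjusted p = 8.35e-04). Set against its 15.7% of protein-coding genes, the X share lay slightly above and was not distinguished (exact binomial p = 0.957), so its direction depends on the reference. The other calls depended on it too, in a test added after the results were seen. Against gene number, chromosome 4 (0.574% of genes) and 2L (19.1%, now slightly above the peak share) lost their calls (exact binomial adjusted p = 0.130 and 0.957). Arms 2R, 3L and 3R did not pass against length (adjusted p 0.946, 0.482 and 0.537). Against gene number, 2R was lower (18.9% against 20.5%, exact binomial adjusted p = 0.0122) and 3L higher (21.5% against 19.6%, adjusted p = 0.00218).

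The next question was whether the DNA word that Gcm recognises marked the summits. The consensus ATRCGGGY lay within 100 bp of 557 summits, 9.76% (interval 9.002 to 10.6), against 1.10% in the left flank, a ratio of 8.84 (9.30% ± 0.186 in the replicates' top peaks, n = 2; exact McNemar adjusted p = 4.71e-100). Of the 12 motifs, 6 passed, all higher at summits. Beside Gcm these were the GATA word, bound by Srp and Pnr, at 38.1% against 30.3% (exact McNemar adjusted p = 8.14e-18), GAGA at 6.61% against 3.42% (1.42e-14) and the promoter element DRE at 2.21% against 0.526% (1.36e-14). The M1BP word stood at 1.12% against 0.350% (3.17e-06) and the homeodomain word at 16.7% against 12.6% (2.68e-09). The Zelda (0.197), Runt (0.0751), ETS (0.628), Stat92E (0.0697), Su(H) (1.00) and E-box (0.234) words did not pass, by adjusted p. Against random windows of equal GC content the homeodomain word lost its call (16.7% against 16.3%, Fisher's exact adjusted p = 0.651), and ETS, E-box and, at lower share, Stat92E passed (0.00379, 2.02e-07 and 7.29e-04). In the strongest 2853 peaks M1BP lost its call (0.596% against 0.491%, exact McNemar adjusted p = 0.720), and with windows of 50 bp each side it had an adjusted p of 0.0614. Runt and Stat92E words, at lower share than the control, passed in several settings. Runt did so in the strongest 2853 peaks (0.0346), without replicate 1 (0.0160), with 50 bp each side (0.0296) and with 250 bp each side (0.0430). Stat92E did so in the strongest 2853 peaks (0.0261), against the right flank (0.00894) and with 250 bp each side (0.0127), where E-box also passed (0.00128).

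Peaks with the Gcm consensus had a median signal of 316 and those without 296, a difference of 5.00 rank percentile points (permutation p = 0.0237). The call was lost in replicate 1 alone, without replicate 3 (4.16 points, permutation p = 0.0685). Replicate 3 alone gave 8.83 points (permutation p = 4.0e-05), and in the strongest 2853 peaks the difference was -4.63 (permutation p = 0.122). The 571 strongest peaks had the consensus in 6.83% of cases (interval 4.90 to 9.22) and the next 571 in 12.3% (9.68 to 15.2). Low shares were not limited to the strongest peaks. Splitting the peaks by signal into 10 groups, the seventh, ninth and last had 6.67%, 7.53% and 8.60%.

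**Figure D4:**
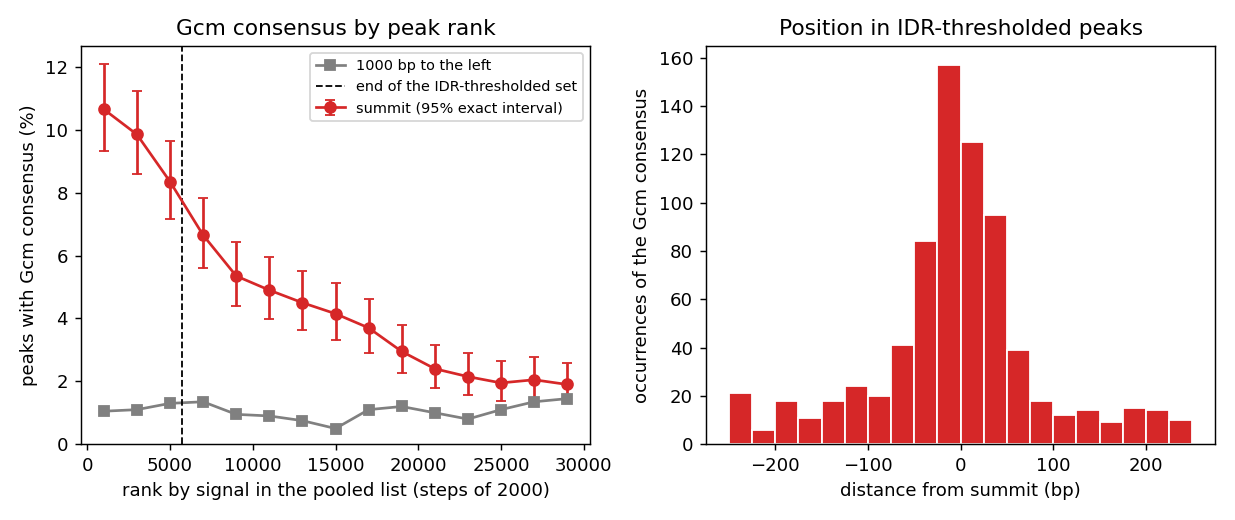
Left, share of pooled-list peaks with the Gcm consensus (y axis, %, exact 95% interval) by rank in steps of 2000 (x axis), falling from 10.7% to 1.90%, with the left flank in grey. Right, occurrences of the consensus (y axis) by distance from the summit of IDR-thresholded peaks (x axis, bp), highest just beside the summit.

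The last question was which gene groups were bound. A summit lay in the territory of 3936 of 13945 genes (28.2%). Cytoplasmic ribosomal protein genes were bound more often than genes of the same length, with 65 of 88 against 17.4 expected (permutation adjusted p = 0.00130; 74.4% ± 4.02, n = 2). Among the highest were RpL34b (signal 1069, though nearest the TSS of CG8132), RpS27 (929) and RpL34a (798). Odorant and gustatory receptor genes were bound less often, 3 of 119 against 27.0 expected (permutation adjusted p = 0.00130; 2.10% ± 0.594, n = 2). With 5 kb of upstream sequence it was 14 of 119 against 38.6 expected, still past the threshold. The 3 genes were Or88a, Or71a and Gr5a, and each peak lay nearest another gene's TSS (CG12402, Plp and Tre1). These 2 of 13 lists passed, and their p was the smallest that a permutation test with 10000 random lists can give. Genes were treated as independent, so these p-values may be too small where members of a list are neighbours. Matching was on length alone and not on promoter activity. The test therefore cannot tell binding particular to these genes from binding at open promoters whatever the motif. Of the 81 peaks at ribosomal protein genes, 96.3% lay at promoters and 1 had the Gcm consensus.

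Of the 23 glial genes, 14 were bound (60.9%, interval 38.5 to 80.3) against 9.11 expected, which did not pass (permutation adjusted p = 0.193). The highest were gcm2 (1341), the FGF receptor gene htl (1330), the engulfment receptor gene drpr (1063, intron, with the Gcm consensus) and moody (859), a receptor gene of the blood-brain barrier. The list passed when only summits within 1 kb of a TSS counted (permutation adjusted p = 0.0234) and in Fisher's exact test without length matching (0.00676). It also passed when only peaks with the Gcm consensus counted (6 of 23 against 1.34 expected, permutation adjusted p = 0.0468), a setting chosen after the results were seen. With only peaks that lack the consensus, 14 of 23 were still bound against 8.73 expected (permutation adjusted p = 0.0910). The list includes gcm, gcm2, repo, pnt, loco and ttk, chosen beforehand as genes known in connection with gcm, and all of these were bound. Of them gcm2, loco, pnt and ttk were among the 6 bound with the consensus. These calls need not hold for the other glial genes, which were not tested apart. Set against each other list by Fisher's exact test without length matching, the glial share differed from the receptors alone (adjusted p = 6.77e-10, over 12 comparisons). The receptors were themselves bound less often than genes of the same length.

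Notch pathway genes had 11 of 18 bound against 6.08 expected and did not pass (permutation adjusted p = 0.0589). They were led by E(spl)m7-HLH (1238), E(spl)mdelta-HLH (1051, nearest CG43116), mam (883, intron, nearest CG18371) and E(spl)m3-HLH (840). The list passed with 5 kb of upstream sequence (permutation adjusted p = 0.00433) and without length matching (Fisher's exact adjusted p = 0.0191). The E(spl) genes named here lie on arm 3R between 25997621 and 26038019, so they are not independent, as both tests assume. Of the neuron genes 6 of 20 were bound against 10.4 expected (permutation adjusted p = 0.196), with elav, an RNA-binding protein gene, at 1722 and rank 64, ChAT at 373 (nearest the TSS of CG34283), Syx1A at 305 and nSyb at 246 (nearest Bgb). Neural precursor genes had 10 of 24 against 9.25 expected (1.00), with brat at 1032, numb at 942, grh at 853 and mira at 745, the last with the consensus.

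The remaining lists did not pass. Plasmatocyte genes gave 7 of 21 against 8.26 expected (permutation adjusted p = 0.9497), led by ush (3309), the receptor gene NimC4 (630), the GATA factor gene srp (525) and Tig (274). The crystal cell list gave 2 of 6 against 2.43 (1.00), PPO3 (509, nearest CG9890) and klu (270, with the consensus). List names are labels, and a member such as PPO3 need not be particular to that cell type. Muscle genes gave 11 of 24 against 10.6 (1.00), with Mef2 at 2099 (nearest Pal1), tin at 1286, kirre at 768 and how at 518. The trachea and epidermis list gave 7 of 10 against 4.87 (0.565), with its members sim at 921, trh at 772, bnl at 478 and pnr at 312. It passed without length matching (Fisher's exact adjusted p = 0.0191). Hedgehog pathway genes gave 6 of 11 against 4.23 (0.681), with ihog at 818 (nearest Gas41), ptc at 490, hh at 326 (nearest CG31457) and boi at 304. JAK/STAT pathway genes gave 6 of 12 against 4.73 (0.913), with Socs36E at 770, ken at 678, Stat92E at 590 and Ptp61F at 513 (nearest SA2). Early patterning genes gave 8 of 17 against 5.59 (0.565), with cad at 669, dpp at 397, wg at 366 and hry at 338. The genes with most summits were kirre (22), jing (21), ush (21), Sema1a (16) and hth (16), all long genes, hth spanning 132008 bp.

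**Figure D5:**
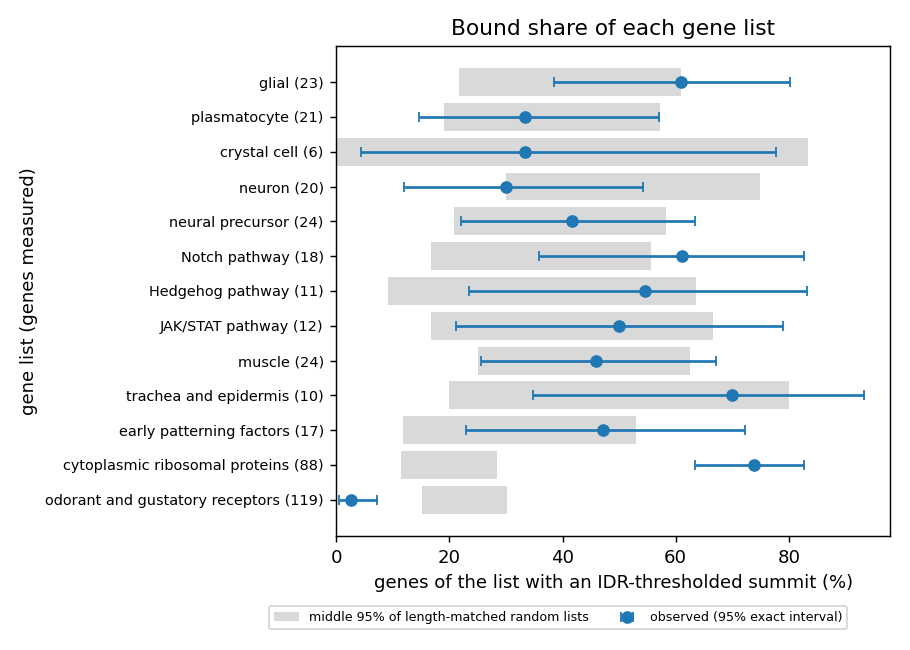
Share of each list's genes with an IDR-thresholded summit (x axis, %, points with exact 95% interval) by list (y axis, number of genes), over the middle 95% of length-matched random lists (grey). Ribosomal protein genes (73.9%) lie above the grey range and receptors (2.52%) below it, and the Notch point (61.1%) lies above it before adjustment.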

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

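The test of lower-ranked pooled peaks was chosen after the motif result had been seen, and the tests of base composition and centring before. Among the 24293 pooled-list peaks below the IDR-thresholded set, whose motifs were outside the report's tests, 873 (3.59%, interval 3.36 to 3.84) had the Gcm consensus within 100 bp of the summit. The left flank, the level without binding used here, had 1.05% (exact McNemar p = 2.69e-81). By rank the share was 6.65% at ranks 6001 to 8000 and 2.95% at 18001 to 20000. In the last 2 steps, from rank 26001, it was 2.05% and 1.90% and no longer differed from the flank (adjusted p 0.117 and 0.321).

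The excess of the Gcm consensus at summits could come from base composition. All orders of the bases of ATGCGGGT were therefore compared, and the ratio of summit to flank for the word itself, 14.7, lay at percentile 100 of 839 others, whose 95th percentile was 1.78, which argues against composition. The highest other, TATGCGGG at 12.4, contains most of the same word and is no independent control. Binding centred on the word is the biological explanation that was tested. Of 751 occurrences within 250 bp, 61.4% (interval 57.8 to 64.9) lay within 50 bp of the summit against 20% under even spread, in line with that hypothesis.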

How the results depend on the processing

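Alternatives that split peaks by the Gcm consensus or by promoter, the motif count at 250 bp and gene number for arms other than X were added after the results had been seen, and the others were planned. Of the results that answer a comparison, 38 values kept their direction and side of the threshold or stayed within 1.5 times a count. Replicate overlap ran from 65.3% with reciprocal overlap of 50% to 81.4% in the strongest 2853 peaks, and the promoter share from 30.9% (250 bp) to 48.2% (1000 bp). The Gcm motif share ran from 3.98% (stricter word) to 13.2% (outside promoters), each above its control. Each replicate alone gave 9.16% to 9.43% for the Gcm motif, 15.6% to 15.7% for X, and 4.16 to 8.83 points for the signal of motif peaks, the lower without replicate 3 and not past the threshold. The rank correlation of peak heights between replicates, a value with no test, moved to 0.802 in the strongest 2853 peaks, 0.799 with the highest overlapping peak and 0.778 with summits within 100 bp. The X share, 15.8%, turned from below to above its reference with gene number in place of length, which changes the reference alone. The same setting turned 2L (19.0%), 2R (18.9%) and 3R (24.4%) from above to below. The signal difference turned to -4.63 in the strongest 2853 peaks, and the cause was not tested. Lists past the threshold numbered 5 without length matching, 1 with only peaks that have the Gcm consensus, where far fewer genes are bound, and 4 with only peaks that lack it, for which the cause was not tested. Single lists, none past the threshold, turned around their expected number: neural precursor at 25% in the strongest 2853 peaks, muscle at 29.2% with a TSS within 1 kb, and plasmatocyte (33.3%), crystal cell (33.3%) and neuron (30%) without length matching. Motifs past the threshold numbered 6 to 9 over all settings, 9 with 250 bp each side. Depth is unknown here, so it could not be related to any value.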

Other observations

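The 8 further gene lists were written after the files had been opened. Tests of all 8-base words, of lists by motif, of promoter against distant peaks, of the strongest peaks and of ribosomal protein peaks were chosen after results had been seen, and the other tests in this part before. Among the further lists, nuclear receptor and ecdysone response genes were bound more often than genes of the same length, 18 of 21 against 10.6 expected (permutation adjusted p = 0.00320). Respiratory chain genes had 26 of 84 against 16.3 (0.0277), and cuticle protein genes were bound less often, 3 of 115 against 21.3 (0.00160). These lists too were matched on length alone, not on promoter activity, and neighbouring members count as independent. The Wnt pathway (13 of 17 against 8.31) and the EGF receptor pathway (11 of 14 against 6.77) did not pass (0.0614 each). Nor did Hox genes (6 of 8 against 4.56, 0.507), septate junction genes (10 of 16 against 6.71, 0.189) or trypsin-like proteases (1 of 17 against 2.62, 0.507). Some genes sit in several lists, such as pnt, svp and Nrg.

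The Gcm consensus was in 14.6% of the 2310 peaks over 2000 bp from a TSS and in 4.48% of promoter peaks (Fisher's exact adjusted p = 1.34e-31). DRE (5.06% at promoters against 0.390%, Fisher's exact adjusted p = 6.48e-25) and M1BP (2.62% against 0.173%, 1.24e-13) showed the opposite, and neither exceeded its flank far from a TSS. E-box (12.5% against 6.58%, 2.09e-11) and GAGA (8.03% against 5.41%, 9.26e-04) were also higher at promoters. GATA was lower there (33.7% against 39.6%, 9.22e-05). The E-box word did not pass against its own flank in either class. At promoters the flank had 10.4% (exact McNemar adjusted p = 0.0618), and far from a TSS it had 7.19%, above the summits. The E-box difference may therefore reflect the regions rather than the summits. With only peaks that have the consensus, the glial genes bound were Lac, drpr, gcm2, loco, pnt and ttk. At repo a peak with the consensus (rank 3261) lay 2082 bp upstream of the TSS, just outside the 2000 bp that counted. With only peaks that lack the consensus, 4 lists passed. Ribosomal protein genes and receptors did so at a permutation adjusted p of 0.00130 each. Neuron genes had a lower number than expected (4 of 20 against 10.03, 0.0355) and Notch pathway genes a higher one (11 of 18 against 5.85, 0.0409). Neighbouring E(spl) genes count as independent in this test, so the Notch p may be too small. Of the 11517 words of 8 bases found at 30 or more summits, ACCCGCAT, a form of the consensus, had the highest ratio of summit to mean flank, with 0.5 added to both numbers of peaks (11.7). A different word, CACTGAGA, was in 171 peaks (3.00% against 0.473%, ratio 6.24, Fisher's exact adjusted p against the left flank = 2.65e-24), overlapping TACACTGA (5.36). It was in 3.22% of peaks without the Gcm consensus and in 0.898% of those with it, a difference that was not tested.

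The 5150 peaks without the Gcm consensus lay at promoters in 41.8% of cases and those with it in 18.1%. The difference was 23.7 percentage points (interval 20.2 to 27.1, Fisher's exact p = 6.39e-30), as binding or capture at open promoters whatever the motif could give. Peaks without the consensus lack an exact match only. A near form, ACCCGCAC, which differs from ACCCGCAT in its last base, was also higher at summits (1.66% of all peaks against 0.385% in the flanks). At ribosomal protein genes 1 of 81 peaks (1.23%, interval up to 6.69) had the consensus against 9.88% of other peaks, so that word accounts for few of them, but among promoter peaks, where 96.3% of them lay, the shares were 1.28% and 4.60% (Fisher's exact p = 0.259). The GAGA or Zelda word lay in 7.42% of peaks without the consensus and in 8.44% of those with it, a difference of -1.02 points (interval -3.44 to 1.40). Most peaks without the consensus thus had neither word within 100 bp, so exact words this close can account for a minority of them at most. Near forms and words further away were not compared between these groups. With 250 bp each side, GAGA lay in 17.2% of all peaks. Whether GAGA-rich or Zelda-bound regions account for some or most of the peaks without the consensus remained open. The strongest 571 peaks had fewer consensus peaks than the rest (odds ratio 0.654), though a weaker group had a share as low (6.67% in the seventh of 10 by signal), and whether promoters account for this cannot be told apart, since outside promoters the odds ratio was 0.870 with an interval, 0.570 to 1.29, that holds both 1 and 0.654, while at promoters the share was also lower, 2.60% against 4.78% (odds ratio 0.531, interval 0.220 to 1.11, Fisher's exact p = 0.102). The design names no biological alternative for these peaks, and the control library was not analysed here.

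The 40 kb around gcm held 41 pooled-list summits, percentile 99.8 among windows centred on protein-coding genes (median 9), and 12 IDR-thresholded ones. The highest lay at brwl (2263) and near jp (2051), not at gcm. A transgene that adds copies of the locus could raise this number, if the line carries it in that form. The labels call the line transgenic and name an insertion targeting gcm, but do not state whether this adds a copy or changes the gene in place. The percentile met what added copies would need. The window around repo, on arm 3R, had 34 (percentile 99.3), a density that copies of gcm would not give, so the test does not single out the transgene. No biological explanation was tested here.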
